A study of Mus musculus with 15 samples.

How the data were processed

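The study measured messenger RNA from the olfactory epithelium of male C57BL/6J mice 8 weeks of age after exposure to a pair of odorants. Ribosomes carrying phosphorylated ribosomal protein S6 were immunoprecipitated from the tissue and the bound RNA was sequenced. Neurons phosphorylate S6 when they are active, so the precipitate is enriched for transcripts of activated cells, the odorant receptors of the responding neurons among them. There were 15 libraries, 3 mice in each of 5 groups. The Control mice received no odorant. The A+D and A&D mice received acetophenone and decanal, and the O+C and O&C mice received octanal and cis-3-hexenol. A plus sign means that both odorants were put on 1 filter paper, and an ampersand means that they were put on 2 papers 1 mm apart. The labels give 3 biological replicates per group, and each library is taken as 1 mouse. No group received a single odorant, so the share of each component in a response cannot be separated by this design.

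The deposited tables hold expected counts, that is, estimated counts per gene that need not be whole, with no normalization by library size. Reads were aligned with STAR 2.7.10b and quantified with Salmon 1.10.1, R 4.4.2 was used, and the genome build was GRCm39, per the submitters' processing notes. The notes do not say which annotation was used or whether strand was taken into account. Between 86.0% and 87.9% of all values in a library, zeros included, were whole numbers to within the 3 decimals given. Genes whose values were not whole in most libraries are taken to share reads with another gene, such as a near-identical copy or an overlapping gene. The named ones are listed as such at the start of the results. The other gene and the number of reads shared were not determined. The tables identify genes by Ensembl gene identifiers, and 52029 of the 57010 identifiers were matched to a symbol in the available name table. The 4981 without a symbol held 0.313% to 0.551% of the counts of a library. The gene annotation at hand was of another build, GRCm38, so it served for names and synonyms only and no position is given.

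Counts were rounded to whole numbers. The total count per library ran from 22704193 to 25287077. Levels are given as CPM, edgeR's library-scaled count after TMM scaling, and counting error and the differences between mice are both included in the errors given. The levels of odorant binding proteins and other gland products in single libraries are the exception. Their CPM was taken over the total count of the library, without TMM scaling. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 19229 genes. Library sizes were scaled by the trimmed mean of M values (TMM). Fold changes, their standard errors and p-values came from edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood F test on 1 model with a mean per group over all 15 libraries, so that the 5 groups share the estimate of the spread. The common dispersion was 0.0336, a biological coefficient of variation of 0.183. The standard error is the size of the log2 fold change divided by the square root of F. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. There were 10 comparisons: each odour group against Control, the delivery methods within each odorant pair (A+D against A&D, O+C against O&C), the difference between these delivery effects (the interaction), the pooled mixtures of each pair against Control, and the pairs against each other.

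Odorant receptor genes were those whose symbol is Olfr and a number. Of these, 1108 are intact and 299 carry a pseudogene suffix. Among the intact genes 867 passed the count filter, 87 of class I and 750 of class II, and 30 had no class. The classes were to be read from receptor family symbols, but the name table gives older symbols, so the family numbers in the synonyms were used instead. Receptor p-values were adjusted over the receptor list alone, and the count after adjustment over all 19229 genes is given beside it. Adjusted p-values of receptor genes are those over the receptor list alone unless the text says otherwise, and those of other genes are over all genes. Pseudogenes were counted neither as receptors nor as other genes where genes are named.

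Each of 29 gene lists was compared with all other genes by limma's camera (limma 3.58.1) with its preset correlation between genes of 0.01, and again with the correlation estimated from the data. The rotation test fry asked whether a list moved on balance one way. Of these lists 22 were written by hand and 7 were taken by symbol. They cover immediate early genes, genes linked to receptor neuron activity, mature and immature olfactory sensory neurons, globose and horizontal basal cells, sustentacular cells, Bowman gland, microvillar cells, ensheathing glia, respiratory ciliated cells, immune cells, red blood cells, endothelial and stromal cells, bone and muscle. They also cover xenobiotic metabolism, aldehyde and alcohol metabolism, NRF2 targets, heat shock, the circadian clock, dorsal and ventral zone neurons, both receptor classes, receptor pseudogenes, trace amine and vomeronasal receptors, cytosolic ribosomal proteins and mitochondrial genes. Gpx6 and Nqo1 each stand in 2 lists. The ribosomal list was taken by symbol and includes kinases such as Rps6ka1. Receptors that respond to a pair of odorants, called responsive receptors, are those higher in the pooled mixtures than in Control. Choosing them gives each delivery method the same weight, so the choice itself does not favour 1 delivery over the other.

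The samples, the groups, the comparisons, the tests, the lists and the alternatives were chosen before the data were examined, and so was the rule for naming genes. For each odour group against Control it names the 10 receptors with the largest rise and the 5 with the largest fall among those called, and the 5 other genes most changed each way. A named gene had a mean of at least 1 CPM, and every library of one group lay above every library of the other. For the delivery comparisons and the interaction it names the 10 receptors most changed, and for the comparison of the pairs the 10 most changed each way. Of the receptors so named for the pairs, only a part is given in the text. From each list it names up to 4 members with the smallest p. Predicted genes without an assigned name count but are not named. Receptors reported for acetophenone or octanal in the literature (Olfr983, Olfr923, Olfr160, Olfr145, Olfr2 and Olfr151) are reported whatever their value, and Olfr151 had too few counts to be tested.

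The share of counts in receptor genes was compared between groups by an exact permutation test. The alternatives were RLE scaling, scaling on the receptor genes alone, no count filter, a stricter filter of at least 1 CPM in 6 libraries, DESeq2 1.42.0, a fit on the compared groups alone, the replicate number as a block, adjustment of receptors over all genes, and leaving out each library in turn. A term for gland transcripts and a fit on the 10 libraries that hold them were added after seeing the data. Unchanged groups were simulated against the same controls for the comparisons that share them. Each result of a fit across genes was also computed for other splits of the libraries. These splits were first defined with reshuffles inside the pooled mixtures as separate splits, and this was corrected after the first counts had been seen.

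The fit was tested on simulated counts drawn from the means over all 15 libraries and from the library sizes. The changed genes were drawn among those with a mean of at least 1 CPM, so recovery at lower levels was not measured. In the simulated A+D against Control comparison over 18962 genes, 17.6% of the receptors changed 1.5-fold, 66.7% of those changed 2-fold and 90.9% of those changed 4-fold were recovered. Of the other genes 6.1%, 76.5% and 97% were recovered at these sizes. The fit called 1 unchanged gene over all genes and 5 unchanged receptors over the receptor list alone. In the simulated O+C against O&C comparison it called none of either. Nothing deposited was left out except genes below the count filter.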

Results

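The data are RNA-seq libraries of messenger RNA that co-precipitated with phosphorylated ribosomal protein S6 from mouse olfactory epithelium, 1 library per mouse, in 5 groups of 3. Control mice received no odorant. A+D and A&D mice were exposed for 90 min to acetophenone and decanal, and O+C and O&C mice to octanal and cis-3-hexenol, with 10 µL of each odorant in every case. Both odorants shared 1 paper in A+D and O+C, and each had its own paper in A&D and O&C. The libraries held between 22704193 and 25287077 counts. Of the 1108 intact odorant receptor genes, 867 had enough counts to be tested. Among the receptors named here, Olfr121, Olfr287, Olfr479, Olfr509, Olfr749, Olfr1197, Olfr1252, Olfr1283, Olfr1383, Olfr1384 and Olfr1426 had counts that were not whole in most libraries. They are thus taken to share reads with another gene, and their values are uncertain to an extent that was not measured. The same holds for Heg1, Lrrc3b, Maff, Gnal, Adcy3, Lyz2 and Akr1b3, whose counts were whole in none of the 15 libraries, and for Pcdh10, Adam17 and Gbp6.

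Receptor transcripts took 0.341% ± 0.0293 of the counts in Control (SD, n = 3), 0.386% ± 0.0595 in A+D, 0.469% ± 0.0155 in A&D, 0.468% ± 0.0148 in O+C and 0.522% ± 0.0859 in O&C. In A&D, O+C and O&C the share exceeded Control by 0.128, 0.127 and 0.181 percentage points, each with exact permutation p = 0.1 (0.133 adjusted over the 4 comparisons), the smallest p that 3 against 3 mice can give. For A+D the difference of 0.0444 points gave exact permutation p = 0.3. That difference was 0.02 without A+D 3, 0.028 without Control 1 and 0.077 without A+D 2. Library A+D 2 stood somewhat apart, with a mean correlation of 0.958 with the other libraries (0.970 to 0.978 for the others) and 2.17% of its counts in ribosomal protein genes (0.923% to 1.54% elsewhere). Secreted odorant binding proteins split the libraries across the groups. Obp2a lay at 109 to 527 CPM in 10 libraries and at 0.169 to 2.03 CPM in Control 1, A+D 2, A&D 1, O&C 1 and O&C 3, and Obp1a, Obp1b and Obp2b followed the same split.

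**Figure D1:**
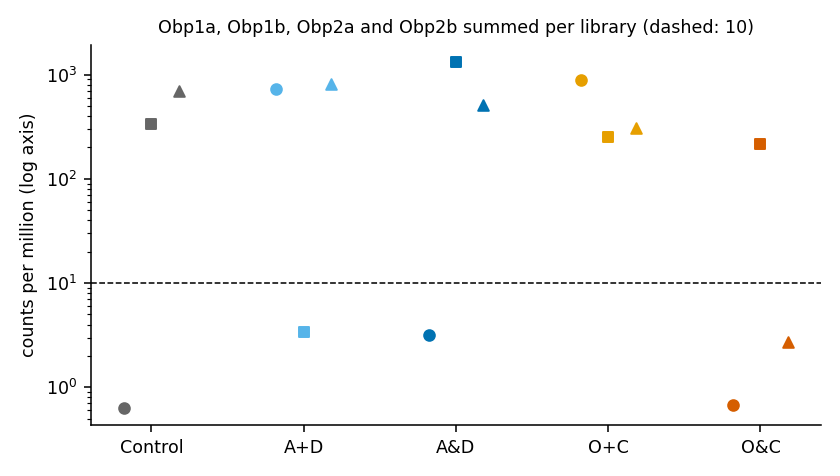
Summed level of Obp1a, Obp1b, Obp2a and Obp2b in each library (CPM without TMM scaling, log axis), by group. Control 1, A+D 2, A&D 1, O&C 1 and O&C 3 lie below the dashed line at 10 CPM and the other 10 libraries above it.

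The comparison of A+D with Control shows which receptors respond when acetophenone and decanal evaporate from 1 paper. Among the receptors named by the rule, Olfr923 (ENSMUSG00000044798) had the largest rise. It went from 0.647 ± 0.135 CPM in Control to 23.1 ± 9.62 CPM in A+D (SD, n = 3), a log2 fold change of 5.15 ± 0.41 (SE, edgeR adjusted p = 1.22e-07). The largest log2 fold change of any receptor called higher was 6.13. Olfr1377 rose from 0.729 ± 0.301 to 15.4 ± 5.56 CPM. Olfr1047 rose by 4.06 ± 0.50 on the log2 scale, Olfr145 by 3.86 ± 0.48, Olfr1026 by 3.80 ± 0.40 and Olfr874 by 3.68 ± 0.29 (adjusted p from 4.63e-08 to 2.71e-05). Olfr922 rose by 3.23 ± 0.42. Olfr287 rose by 3.24 ± 0.18, with shared reads. Olfr876 rose by 3.31 ± 0.52, or by 3.99 without Control 2. Olfr881 rose by 3.36 ± 0.77 (adjusted p = 0.00962), and lost its call without Control 1 or Control 3 (adjusted p up to 0.0523). Of the 867 receptors, 70 were higher and 1 lower, adjusted over the list alone, and 46 were called over all genes, each of them higher. The lower count was 8 without A+D 1, 6 without Control 1, 5 without A+D 3, 2 without Control 3 and 0 without Control 2, all by edgeR. Class I gave 3 of the higher receptors and class II gave 66. The median log2 fold change was 2.03 among the higher receptors and -0.11 among the rest. The lower receptor, Olfr1197, which shares reads, fell by 0.76 ± 0.20 (edgeR adjusted p = 0.0221). Its call was lost without Control 2 (adjusted p = 0.177), A+D 1, A+D 2 or A+D 3, and with library sizes scaled on the receptors alone (adjusted p = 0.139).

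Outside the receptors, 12 genes were called in A+D. Heg1 rose from 19.8 ± 1.95 to 37.3 ± 3.36 CPM, a log2 fold change of 0.91 ± 0.14 (edgeR adjusted p = 0.00269), and it stayed called without each of the 6 libraries. Ildr2 (1.58), Kcng1 (1.20), Scgn (0.78), Slc18a1 (-1.28), Ccr1 (-0.84), Mmp13 (-0.82), Parvg (-0.72) and Sfrp4 (-0.72) were also called, with adjusted p from 0.0181 to 0.0496. Each of these lost its call without several of Control 1, Control 2, Control 3, A+D 2 and A+D 3 (adjusted p up to 0.322). Over all genes 57 were higher and 5 lower. Without A+D 1 these became 369 and 158, and the lower count was 19 without Control 3, 1 without Control 1 or A+D 3 and 0 without Control 2. Genes linked to receptor neuron activity had a median log2 fold change of 0.76, with 3 of 5 called adjusted over the list alone and none over all genes. Camera gave that list an adjusted p of 1.17e-04, and adjusted p = 0.569 with an estimated correlation. Mature olfactory sensory neuron genes had a median of 0.19 (0.000604, and adjusted p = 0.569 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.37 and mitochondrial transcripts one of 0.61 (adjusted p = 3.29e-09 and 0.0049, both 0.605 with an estimated correlation), beside the high ribosomal share of A+D 2. Camera also called immature sensory neurons (0.24), sustentacular cells (-0.24), aldehyde and alcohol metabolism (-0.24), xenobiotic metabolism (-0.15) and class I receptors (-0.26), with adjusted p from 0.000352 to 0.0322, and from 0.569 to 0.705 with an estimated correlation. Without A+D 2 ribosomal proteins stood at 0.02, mitochondrial transcripts at 0.30 and immature neurons at 0.12 and lost their calls (up to 0.676), and mature neurons stood at 0.30. Ribosomal proteins were at 0.25 without Control 1, and xenobiotic metabolism at -0.27 without A+D 1 and about as low without Control 3. Class I lost its call without Control 2 (0.00), A+D 1 (-0.25) or A+D 2 (-0.10), and stood at -0.42 without Control 1 and lower still without A+D 3.

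Against Control, A&D shows which receptors respond when the same odorants evaporate from separate papers. Olfr1047 (ENSMUSG00000075196) rose from 0.190 ± 0.105 CPM to 6.82 ± 1.79 CPM (SD, n = 3), a log2 fold change of 5.13 ± 0.50 (edgeR adjusted p = 2.13e-07). Olfr923 rose by 5.11 ± 0.41, Olfr1377 by 4.74 ± 0.39, Olfr1026 by 4.59 ± 0.40, Olfr874 by 4.46 ± 0.29, Olfr922 by 4.43 ± 0.42 and Olfr117 by 4.34 ± 0.36. Olfr218 rose by 4.41 ± 0.48 (5.10 without Control 3) and Olfr904 by 4.28 ± 0.43 (4.87 without Control 2). All these receptors, and Olfr145 at 4.37 ± 0.48, stayed called without each of the 6 libraries. Of the 867 receptors, 104 were higher and 3 lower, adjusted over the list alone, and 89 were called over all genes, each of them higher. The higher receptors had a median of 2.63, and 100 of them rose more than 2-fold. The lower count was 5 without Control 1 and 0 without A&D 3. The higher ones were 5 of class I, where Olfr455 rose by 1.65 and Olfr569 by 3.26, and 98 of class II. Among the lower receptors, Olfr523 (-0.80) and Olfr309 (-0.64) had adjusted p = 0.0414 and 0.017 and lost their calls, Olfr523 without each library but Control 3 and Olfr309 without Control 3, A&D 2 or A&D 3 (adjusted p up to 0.158). The receptors reported for acetophenone were higher in both deliveries. Olfr983 rose by 3.06 in A+D and 3.59 in A&D, and Olfr160 by 1.71 and 2.61 (edgeR adjusted p from 4.47e-10 to 0.00594).

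**Figure D2:**
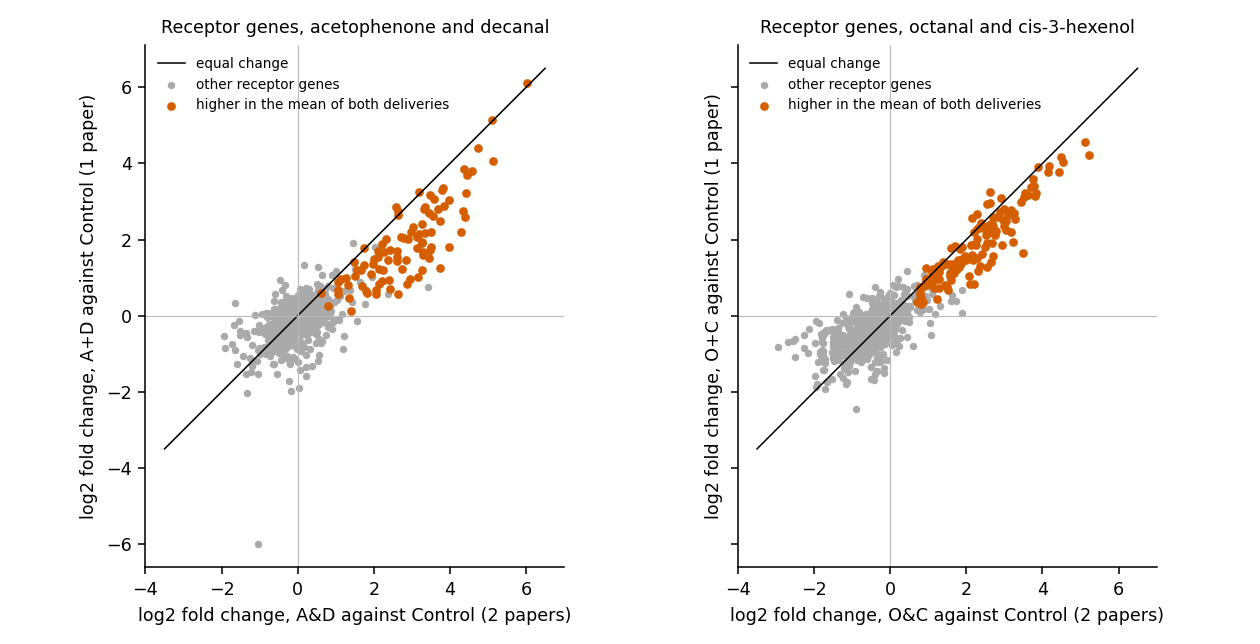
Log2 fold change of each tested receptor against Control with the odorants on separate papers (horizontal axis) and on 1 paper (vertical axis), for acetophenone and decanal (left) and octanal and cis-3-hexenol (right), with responsive receptors coloured and a line at equal change. All 70 receptors higher in A+D lie among the 104 higher in A&D, and all 106 higher in O+C among the 143 higher in O&C.

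Among other genes, 103 were called in A&D, and over all genes 193 were higher and 4 lower. The higher count was 111 without Control 1, 130 without Control 2, 126 without Control 3, 122 without A&D 1 and 126 without A&D 2, and the lower count ran from 0 without Control 2 or A&D 1 to 26 without A&D 3, with 1 without Control 1, 12 without Control 3 and 2 without A&D 2. Kcng1 rose by 1.87 ± 0.23, Lrrc3b by 1.70 ± 0.23 and Pcdh10 by 2.35 ± 0.37 (edgeR adjusted p = 0.000129, 0.000475 and 0.00431). The immediate early gene Nr4a1 (ENSMUSG00000023034) rose from 37.5 ± 6.26 to 80.4 ± 9.0 CPM (adjusted p = 0.000283), while its level in A+D was 37.7 ± 3.82 CPM. Ildr2 (1.62, adjusted p = 0.0153) was lost without Control 1, Control 2, Control 3 or A&D 2 (up to 0.0985). Tbx3 (-1.25), Pde4b (-0.73), Adam17 (-0.65) and Litaf (-0.48) were lower, with adjusted p up to 0.0369, and Pde4b and Adam17 lost their calls without any 1 of the 6 libraries, Tbx3 without Control 2, Control 3, A&D 1 or A&D 2, and Litaf without Control 1, Control 2, A&D 1 or A&D 2 (up to 0.212). Of the 5 activity-linked genes 3 were higher over all genes and 5 adjusted over the list alone, with a median of 0.93 (6.87e-11, and adjusted p = 0.0812 with an estimated correlation). Of 21 mature sensory neuron genes 3 and 14 were higher, with a median of 0.43 (2.08e-10, and adjusted p = 0.295 with an estimated correlation). The fry test called both lists (0.0145 and 0.0382). Sustentacular cell genes had a median of -0.30 and aldehyde and alcohol metabolism genes one of -0.28 (1.15e-05 and 1.1e-05, both adjusted p = 0.391 with an estimated correlation). Class II receptors had a median of -0.02 but a mean of 0.29 and a test direction of higher (3.58e-07, and adjusted p = 0.391 with an estimated correlation). Camera also called horizontal basal cells (-0.39), ensheathing glia (-0.28), xenobiotic metabolism (-0.28), ribosomal proteins (0.16) and mitochondrial transcripts (0.48), with adjusted p from 0.0024 to 0.0474, and from 0.391 to 0.904 with an estimated correlation. Library A&D 1 had the highest mitochondrial share (0.202%), and without it mitochondrial transcripts stood at 0.00 and ribosomal proteins at 0.04. Both lost their calls there and without Control 1 (0.38 and 0.04) or Control 2 (0.47 and 0.14), and rose to 0.73 without A&D 3 and 0.34 without Control 3. Horizontal basal cells lost their call without any library but A&D 1 (-0.22 without A&D 2), and ensheathing glia without Control 3, A&D 1 or A&D 2 (up to 0.135). The class II median lay between -0.11 without Control 1 and 0.08 without Control 2.

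The O+C mice against Control show the response to octanal and cis-3-hexenol from 1 paper. Olfr1383 (ENSMUSG00000107417) rose from 2.35 ± 0.675 to 55.1 ± 3.71 CPM (SD, n = 3), a log2 fold change of 4.55 ± 0.34 (edgeR adjusted p = 7.38e-08), with shared reads. Olfr1364 rose from 10.1 ± 0.657 to 121 ± 27.5 CPM (3.58 ± 0.16, adjusted p = 2.82e-11). Olfr847 rose by 4.23 ± 0.48, Olfr1116 by 4.18 ± 0.31, Olfr1408 by 4.03 ± 0.31, Olfr509 by 3.94 ± 0.32, Olfr117 and Olfr332 by 3.78 each and Olfr984 by 3.42 ± 0.29. Olfr218 rose by 3.90 ± 0.48, or 4.59 without Control 3. These calls held without each of the 6 libraries. Of the 867 receptors, 106 were higher and 44 lower, adjusted over the list alone, and 99 and 32 over all genes. The 44 lower receptors became 23 without O+C 1, 24 without Control 3 and 28 without Control 2. Scaled on the receptors alone, the split was 135 higher and 8 lower, and the median of all receptors moved up by 0.26 from -0.33. Olfr1283 fell by 1.34 ± 0.31 and Olfr1252 by 1.32 ± 0.27, both with shared reads (adjusted p = 0.00451 and 0.00174), and both stayed lower with that scaling (-1.09 and -1.06). Olfr738 (-1.22) was no longer called with it (adjusted p = 0.078). Olfr1031 (-1.67) lost its call without Control 3 (adjusted p = 0.061), and Olfr981 (-1.20) without Control 2, Control 3 or O+C 1 (up to 0.0638). Olfr2, reported for octanal, rose by 2.34 in O+C and 2.33 in O&C (8.47e-09 and 5.98e-09).

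Over all genes 1104 were higher and 451 lower in O+C, of which 1415 were not receptors. These became 636 and 107 without Control 1, 647 and 187 without Control 2, 552 and 241 without Control 3, 476 and 66 without O+C 1, 908 and 298 without O+C 2, and 821 and 145 without O+C 3. Nr4a1 rose to 244 ± 43.1 CPM, a log2 fold change of 2.71 ± 0.16 (edgeR adjusted p = 1.52e-08), and Egr4 by 2.11 and Maff by 1.25. Kcng1 rose from 10.1 ± 2.93 to 65.8 ± 19.9 CPM and Pcdh10 by 2.72 ± 0.37. Fosb (2.60) lost its call without Control 2 or Control 3 (0.0573 and 0.0543). Tmem150cos (3.43) dropped to 1.48 without O+C 1 (adjusted p = 0.0951) and lost its call without each Control as well. Gbp6 (-2.38), Sprr2a2 (-2.28), Slc6a13 (-1.98), Krt15 (-1.87) and Kcnj8 (-1.61) were lower, each losing its call without O+C 1 and without 1 to 3 of the other libraries, of Control as well as O+C (adjusted p up to 0.248). Sprr2a2 stood at -1.21 without Control 3, Krt15 at -1.23 without Control 2 and Gbp6 at -1.51 without Control 1. All 5 activity-linked genes were higher, Lrrc3b by 2.10, Sema7a by 1.59 and Kirrel2 by 1.51, with a list median of 1.51 (1.3e-12, and adjusted p = 0.0448 with an estimated correlation). Of 21 mature sensory neuron genes 17 were higher, 20 adjusted over the list alone, among them Gfy (1.19), Umodl1 (1.03), Adcy3 (0.94) and Gnal (0.79), with a median of 0.77 (7.3e-20, and adjusted p = 0.0448 with an estimated correlation). The estimated p of the activity list rose above 0.05 without Control 1, Control 2, Control 3, O+C 2 or O+C 3, and that of the neuron list without any 1 of the 6 libraries (up to 0.0792), while fry stayed at or below 0.0068. Immediate early genes had a median of 0.24, a mean of 0.62 and 7 of 22 higher, 8 adjusted over the list alone (1.02e-04, and adjusted p = 0.16 with an estimated correlation). The other lists called by camera were all lower. They were immune cells (-0.85), sustentacular cells (-0.42), aldehyde and alcohol metabolism (-0.42), xenobiotic metabolism (-0.37), ensheathing glia (-0.58), globose (-0.21) and horizontal basal cells (-0.45), Bowman gland (-0.40), respiratory ciliated cells (-0.30), red blood cells (-0.45), endothelial and stromal cells (-0.41), class I receptors (-0.49) and ribosomal proteins, which had a median of -0.27. Their adjusted p ran from 1.18e-08 to 0.0375, and from 0.172 to 0.686 with an estimated correlation. Globose cells lost their call without Control 3 (-0.14), O+C 1 or O+C 2, horizontal basal cells without Control 1 (-0.22), Control 3, O+C 1 (-0.17) or O+C 3, and ciliated cells without Control 1, Control 3 or O+C 2. Red blood cells lost theirs without Control 3, O+C 1 or O+C 3, stromal cells without O+C 1, class I without Control 2 (-0.18), O+C 1 or O+C 2, and ribosomal proteins without Control 3 (-0.10, and -0.18 without O+C 1), with adjusted p up to 0.403. Bowman gland stood at -0.68 without O+C 1.

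For O&C against Control, the same odorants came from separate papers. Olfr847 (ENSMUSG00000059821) rose from 0.514 ± 0.134 to 19.3 ± 8.49 CPM (SD, n = 3), a log2 fold change of 5.22 ± 0.48 (edgeR adjusted p = 3.08e-07). Olfr1383 rose by 5.12 ± 0.34, Olfr1408 by 4.54 ± 0.32, Olfr1116 by 4.50 ± 0.31, Olfr117 by 4.42, Olfr509 by 4.18 ± 0.32, Olfr332 by 4.16, Olfr1170 by 3.84 ± 0.21 and Olfr1167 by 3.81 ± 0.50. Olfr218 rose by 3.87, or 4.56 without Control 3. Of the 867 receptors, 143 were higher and 110 lower, adjusted over the list alone, and 135 and 71 over all genes. The 110 lower receptors became 31 without O&C 1, 50 without Control 2, 57 without Control 3 and 60 without O&C 3, and without Control 1 there were 124 higher and 127 lower. Scaled on the receptors alone, the split was 150 higher and 32 lower. Class I gave 4 higher and 14 lower receptors, class II 131 and 92. Olfr1030 fell from 1.96 ± 0.520 to 0.444 ± 0.141 CPM (-2.13 ± 0.36, adjusted p = 0.000152). Olfr889 (-1.80) and the class I receptor Olfr615 (-1.78) were also lower, and all 3 kept their calls when scaled on the receptors alone. The class I receptor Olfr642 (-2.50, adjusted p = 0.0114) lost its call without O&C 1 (0.0555). Olfr904, also called lower, had at most 3 counts in an O&C library, so no fold is given for it. Its call (adjusted p = 0.0388) was lost without Control 2, O&C 1, O&C 2 or O&C 3 (up to 0.223) and when scaled on the receptors alone (0.121).

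In O&C 1794 genes were higher and 1040 lower over all genes, of which 2618 were not receptors. These became 1231 and 496 without Control 1, 1250 and 539 without Control 2, 1154 and 672 without Control 3, 1551 and 545 without O&C 1, and 1021 and 253 without O&C 3. Kcng1 rose by 2.85 ± 0.23, Pcdh10 by 2.76 ± 0.37, Lrrc3b by 2.45 ± 0.23, Nr4a1 by 2.30 and Maff by 1.52. Tmem150cos rose by 4.34 ± 0.84 (edgeR adjusted p = 0.00391). Tacr1 fell from 2.89 ± 0.971 to 0.849 ± 0.355 CPM (-1.77 ± 0.39, adjusted p = 0.00592). Sprr2a2 (-2.77) stood at -1.70 without Control 3 (adjusted p = 0.0733), and Krt15 (-1.60) at -0.97 without Control 2 (0.146), with its call also lost without O&C 1 or O&C 3. Serpind1 (-1.66) lost its call without Control 2 or O&C 3 (up to 0.0591). The activity-linked list had a median of 1.77 and the mature sensory neuron list one of 0.86, with 5 of 5 and 19 of 21 genes higher (1.82e-13 and 6.55e-22, both adjusted p = 0.0371 with an estimated correlation). Without Control 1, Control 2, Control 3 or O&C 2 that p rose above 0.05 for both (up to 0.0616). Immediate early genes had a median of 0.41, with 9 of 22 higher and 1 lower over all genes and 10 and 3 adjusted over the list alone (0.000416, and adjusted p = 0.236 with an estimated correlation). Red blood cell genes had a median of -0.87 (0.000513, and 0.261 with an estimated correlation), and mitochondrial transcripts one of -0.84 (0.000796, and 0.559). Camera also called sustentacular cells (-0.43), Bowman gland (-0.73), immune cells (-0.77), globose (-0.34) and horizontal basal cells (-0.45), respiratory ciliated cells (-0.41), xenobiotic metabolism (-0.46), aldehyde and alcohol metabolism (-0.38), class I receptors (-0.74) and ribosomal proteins (-0.30), with adjusted p from 3.1e-06 to 0.0409, and from 0.261 to 0.689 with an estimated correlation. Horizontal basal cells lost their call without any library but O&C 2 (up to 0.135, and -0.26 without O&C 3). Class I stood at -0.46 without Control 2, ribosomal proteins at -0.15 without Control 3 and ciliated cells at -0.26 without Control 1.

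The delivery of acetophenone and decanal was compared directly, A+D against A&D. The receptors that differed were lower from 1 paper, 39 of 867 adjusted over the list alone and 21 over all genes, with none higher by edgeR or DESeq2 (109 receptors had an unadjusted p under 0.05). All 39 were of class II, as were 750 of the 867 receptors tested. Of the 94 receptors higher in the pooled A/D mixtures, class II gave 90. Olfr1408 (ENSMUSG00000062527) stood at 4.13 ± 0.976 CPM in A+D and 23.2 ± 9.10 CPM in A&D (SD, n = 3), against 1.73 ± 0.487 CPM in Control, a log2 fold change of -2.49 ± 0.29 (edgeR adjusted p = 3.51e-05). Olfr1383 was at -2.15 ± 0.30, Olfr509 at -2.14 ± 0.29, Olfr904 at -2.09 ± 0.37, Olfr332 at -2.06 ± 0.33, Olfr1404 at -2.05 ± 0.22, Olfr1344 at -2.05 ± 0.37, Olfr803 at -1.98 and Olfr479 at -1.93 ± 0.23 (adjusted p from 1.48e-05 to 0.0022). Olfr218 (-1.81, adjusted p = 0.0131) lost its call without A+D 1, A+D 2, A&D 1 or A&D 2 (up to 0.129). Outside the receptors Nr4a1 was the 1 gene called (-1.09 ± 0.15, adjusted p = 0.00243). Over all genes 23 were lower, and 12 without A+D 1, 10 without A+D 3 and 11 without A&D 1 or A&D 2. The acetophenone receptors were not called apart, with Olfr923 at 0.04 (adjusted p = 0.985), Olfr983 at -0.53 (0.156), Olfr145 at -0.51 (0.77) and Olfr160 at -0.90 (0.251). The activity-linked list had a median of -0.36 (camera 0.000317, and adjusted p = 0.542 with an estimated correlation), immediate early genes -0.27 (1.25e-06, and 0.122), mature sensory neurons -0.18 (0.000153, and 0.542), immature sensory neurons 0.22 (0.00113, and 0.542) and ensheathing glia 0.28 (0.00546, and 0.542). Ribosomal proteins were at 0.22 (2.93e-06, and 0.905), class I receptors at -0.17 (0.000317, and 0.905) and class II receptors at -0.08 (3.77e-07, and 0.542), beside the high ribosomal share of A+D 2. Without A+D 2 ribosomal proteins turned to -0.13, and mature neurons (-0.08), immature neurons (0.07), ensheathing glia (0.08), class I (-0.05) and class II (0.01) lost their calls (up to 0.947). Class I also lost its call without A&D 1 (-0.04), and ensheathing glia without A+D 1 (0.14), A&D 1 (0.16) or A&D 2 (0.21). Without A+D 3 mature neurons stood at -0.28, ensheathing glia at 0.46, class I at -0.52, class II at -0.18 and ribosomal proteins at 0.35. Ribosomal proteins and class II were at 0.38 and -0.14 without A+D 1. Without A&D 3 ribosomal proteins were at 0.14, immature neurons at 0.15 and class I near -0.3.

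**Figure D3:**
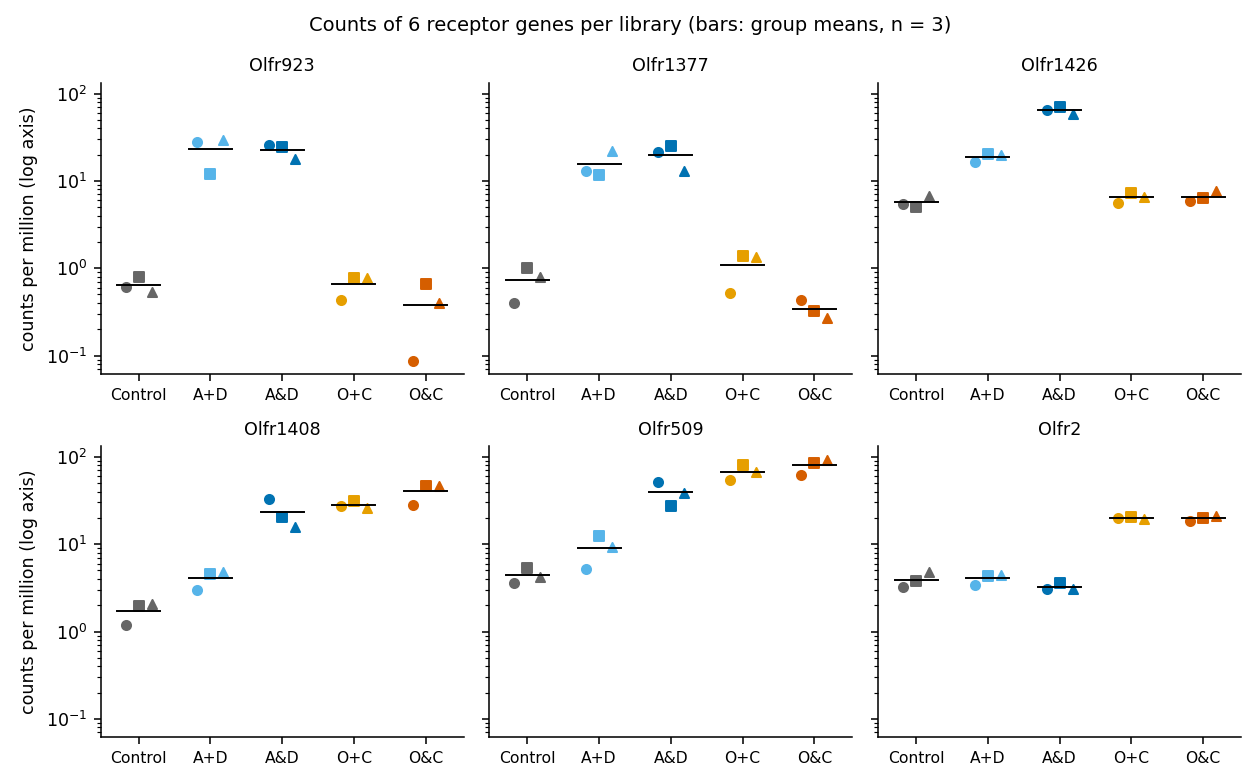
Level of 6 receptors in each library (CPM, log axis), with a bar at the mean of each group of 3. Olfr1408 lies at 3.02 to 4.85 CPM in the A+D libraries and at 15.7 to 33.3 CPM in the A&D libraries, while Olfr923 overlaps between them (12.1 to 29.2 and 17.6 to 25.4 CPM).

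The 94 receptors higher in the pooled A/D mixtures than in Control are called responsive here. Their median log2 fold change, A+D against A&D, was -0.88 (quartiles -1.31 and -0.49), and 87 of the 94 were lower in A+D. The set test with an estimated correlation gave p = 4.59e-06 and fry p = 1.17e-05, and the other 773 receptors had a median of -0.03. The mean level of the 94 receptors was 2.35, 2.38 and 2.59 log2 CPM in the A+D libraries, 3.51, 3.36 and 3.25 in the A&D libraries, and 0.49, 0.81 and 0.68 in Control. The A+D and A&D libraries thus did not overlap, while the gap to Control follows from the choice of the receptors. Of the 39 receptors called lower, 36 belonged to this set. Scaled on the receptors alone, the median was -0.73. Leaving out any 1 library kept the median between -0.98 and -0.78, with a p of at most 0.000264 in the set test with an estimated correlation (limma).

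**Figure D4:**
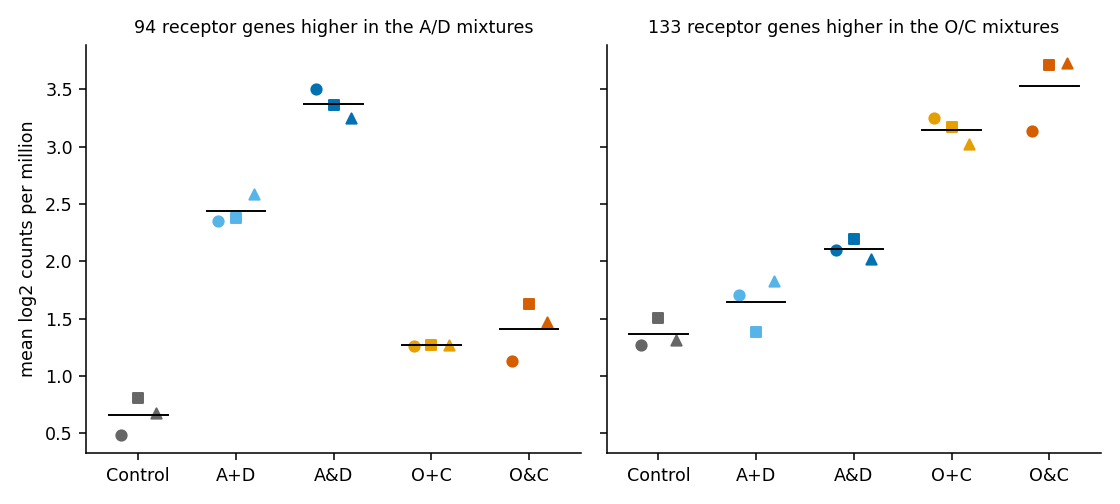
Mean level of the responsive receptors of each odorant pair in each library (log2 CPM), by group. The A/D set lies between 2.35 and 2.59 in the A+D libraries and between 3.25 and 3.51 in the A&D libraries.

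The same comparison for octanal and cis-3-hexenol, O+C against O&C, called 1 receptor higher and 2 lower, adjusted over the list alone. Olfr1404 (ENSMUSG00000049456) stood at 10.2 ± 1.92 CPM in O+C and 25.2 ± 5.45 CPM in O&C (SD, n = 3), against 2.69 ± 0.235 CPM in Control, a log2 fold change of -1.30 ± 0.21 (edgeR adjusted p = 0.00685). Olfr1384, which shares reads, was at -1.27 ± 0.24 (0.0251) and Olfr1030 at 1.79 ± 0.36 (0.0298). Olfr1404 lost its call without O+C 3 or O&C 2 (up to 0.123). The 3 calls became 10 without O&C 1, 1 without O+C 2 or O&C 3 and 0 without O+C 3 or O&C 2 (adjusted p up to 0.213), and 2 higher and 10 lower when scaled on the receptors alone. Over all genes 0 were called by edgeR, where 766 had an unadjusted p under 0.05 and DESeq2 called 9. The 133 receptors responsive to O/C had a median of -0.39 (quartiles -0.55 and -0.16), with 116 lower in O+C (estimated correlation p = 0.0177, fry p = 0.037). Leaving out each library gave medians from -0.56 to -0.29, and p rose above 0.05 without O&C 2 or O&C 3 (up to 0.092). Mitochondrial transcripts had a median of 0.62 (camera 0.00077, and adjusted p = 0.859 with an estimated correlation). The activity-linked list was at -0.27 (0.0107), mature sensory neurons at -0.15 (0.00122), globose basal cells at 0.10 (0.00693), ensheathing glia at -0.26 (0.0337), red blood cells at 0.32 (0.00429) and ventral zone neurons at 0.26 (0.0337), each with adjusted p = 0.859 with an estimated correlation. Class I receptors were at 0.22 (0.00779, and 0.959). Each of these 8 lists lost its call without at least 1 library. Mitochondrial transcripts rested on O+C 3, without which they stood at 0.14 (0.631), and ensheathing glia on O&C 1 (-0.03, 0.956) and O+C 1 (-0.15). Ensheathing glia stood at -0.42 without O&C 2 and -0.39 without O&C 3. The activity-linked list was lost without O+C 2, O+C 3 or O&C 3 (-0.07), and mature neurons without O&C 3 (-0.06), and they stood at -0.47 and -0.25 without O&C 1 and -0.46 and -0.24 without O+C 1. Globose cells were lost without O+C 3 (0.05, and 0.17 without O+C 1), red blood cells without O+C 2 (0.18) or O&C 2 (0.19), ventral zone neurons without O+C 3 (0.11), O&C 1 or O&C 3, and class I without O+C 3 (-0.03) or O&C 1 (0.10), standing at 0.36 without O+C 2 and 0.52 without O&C 2.

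Whether the delivery effect differs between the odorant pairs was tested as the interaction, with negative values where 1 paper lowered the level more for A/D. Olfr1426 (ENSMUSG00000044994) stood at 18.8 ± 2.23 CPM in A+D and 64.1 ± 5.70 CPM in A&D, but at 6.45 ± 0.819 in O+C, 6.60 ± 0.918 in O&C and 5.71 ± 0.872 in Control (SD, n = 3). Its difference of delivery effects was -1.73 ± 0.22 on the log2 scale (edgeR adjusted p = 0.00023, and 0.0051 over all genes), it kept its call without each of the 12 libraries, and it shares reads. Of the receptors that follow, Olfr1408 alone does not. Olfr1426, Olfr749 and Olfr121 were not higher in O/C. Olfr1408 (-1.98), Olfr509 (-1.90), Olfr479 (-1.54), Olfr749 (-1.51) and Olfr121 (-1.22) were also called (adjusted p from 0.0105 to 0.0381), which makes 6 receptors lower and 1 of them over all genes. Olfr749 lost its call without O+C 2 (0.0503), and Olfr1408 without A+D 1, A+D 2, O+C 1 or O+C 2 (up to 0.0904). Olfr509 lost it without any library but A&D 2, Olfr121 without any but A+D 2 and O&C 2, and Olfr479 without A+D 2, A&D 1, A&D 2, O+C 1, O+C 2, O&C 1 or O&C 3 (up to 0.131). The count was 3 without A+D 1, A+D 2 or A&D 1, 2 without O+C 1 and 1 without O+C 2, and it was 1 higher and 3 lower without O&C 1. Scaled on the receptors alone it was 1 higher and 8 lower, without Olfr121 (adjusted p = 0.139). Nr4a1 had -1.50 ± 0.21 (adjusted p = 0.0115), with delivery effects of -1.09 for A/D and 0.41 for O/C, and lost its call without A&D 2 (0.0712) or O&C 1 (0.053). Over the 94 A/D-responsive receptors the median difference was -0.78 (estimated correlation p = 0.000198, fry p = 0.000939), between -0.91 and -0.61 without any 1 library (highest p = 0.00246). As 60 of the 94 were not higher in O/C, this follows in part from the choice of the set. Over the 34 receptors higher in both pairs the median difference was -0.58 (estimated correlation p = 0.000709, fry p = 0.00298), between -0.72 and -0.39 without any 1 library (highest p = 0.00648). Over the 133 O/C-responsive receptors it was 0.05 (limma, estimated correlation p = 0.599). As 99 of the 133 were not higher in A/D, this value also follows in part from the choice of the set. Class I receptors had a median of -0.47 (camera 3.54e-07, and adjusted p = 0.978 with an estimated correlation), and ensheathing glia one of 0.81 (5.91e-05, and 0.565). Immediate early genes were at -0.19 (0.000592, and 0.565). Class II receptors were at -0.11 (0.00162), ribosomal proteins at 0.17 (0.0113), red blood cells at -0.34 and mitochondrial transcripts at -0.56 (both 0.0391), all 0.978 with an estimated correlation. These lists rested on few libraries. Ensheathing glia stood at 0.41 without A+D 2 and 0.40 without O&C 1, still called. Class I lost its call without A+D 2 (-0.29) and stood at -0.22 without A&D 1, -0.29 without O+C 3 and -0.74 without A+D 3. Class II was lost without A+D 2 (0.00), O+C 2 or O&C 1 (0.02), and at -0.19 without A+D 3 and -0.21 without O&C 2. Ribosomal proteins turned to -0.17 without A+D 2 and were lost without A&D 2, A&D 3, O+C 1 (0.08) or O&C 1, with 0.32, 0.30 and 0.27 without A+D 1, A+D 3 and A&D 1. Mitochondrial transcripts were lost without A+D 1 (-0.37), A+D 3, A&D 1 (-0.14), O+C 3 (-0.07), O&C 2 or O&C 3 and stood at -0.90 without A+D 2, and red blood cells were lost without A+D 1, A+D 2, A&D 1 (-0.12), A&D 3, O+C 2 (-0.20) or O&C 2 (-0.21) and stood at -0.51 without A&D 2. Immediate early genes kept their call, at -0.40 without A+D 2, -0.38 without O&C 1 and between -0.12 and -0.09 without A+D 3, A&D 1, A&D 3, O+C 3 or O&C 2.

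Both deliveries were pooled to compare each pair with Control. The pooled A/D mixtures had 94 receptors higher and 4 lower, adjusted over the list alone, and 80 over all genes, each of them higher. The lower count was 12 without A+D 1, 8 without A+D 3, 7 without A&D 2 and 2 without Control 2 or Control 3. The pooled O/C mixtures had 133 higher and 149 lower (126 and 104 over all genes), and 150 and 31 when scaled on the receptors alone. The O/C split was 129 and 57 without Control 2, 116 and 74 without Control 3, 124 and 90 without O+C 1, and 140 and 86 without O&C 1. Olfr983 was lower in O/C (-0.85, edgeR adjusted p = 0.00267), and at -0.60 (0.0467) when scaled on the receptors alone. Olfr923 (-0.36, edgeR adjusted p = 0.564), Olfr160 (-0.85, 0.0819) and Olfr145 (-0.695, 0.303) were not called in O/C. Olfr2 was not called in A/D (-0.12, edgeR adjusted p = 0.816). Receptors not higher in O/C had a median of -0.48. There were 34 receptors higher in both pairs, with medians of 2.31 in A/D and 2.40 in O/C, 60 higher in A/D alone and 99 in O/C alone. Over all genes A/D gave 185 higher and 50 lower. These became 80 and 4 without Control 1, 94 and 0 without Control 2, 116 and 64 without Control 3, 458 and 244 without A+D 1, 233 and 121 without A+D 2, 131 and 9 without A+D 3, 124 and 9 without A&D 1, 126 and 9 without A&D 2, and 193 and 100 without A&D 3. For O/C there were 1939 higher and 1353 lower, which became 1272 and 582 without Control 1, 1267 and 636 without Control 2, 1151 and 792 without Control 3, 1501 and 877 without O+C 1, and 1515 and 760 without O&C 3.

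In the pooled A/D mixtures camera called the activity-linked list (median 0.86), mature sensory neurons (0.31), sustentacular cells (-0.28), aldehyde and alcohol metabolism (-0.25), xenobiotic metabolism (-0.21), horizontal basal cells (-0.29), ribosomal proteins (0.27), mitochondrial transcripts (0.58) and class II receptors, which had a median of -0.025 but a mean of 0.20. The adjusted p of these lists ran from 4.6e-08 to 0.0455, and from 0.199 to 0.697 with an estimated correlation. The class II median lay between -0.10 and 0.04 without any 1 library. Horizontal basal cells lost their call without any library but A+D 1 and A&D 1, class II without Control 1, ribosomal proteins without Control 1 (0.14), and mitochondrial transcripts without Control 1, A+D 2 (0.35) or A&D 1 (0.30), with adjusted p up to 0.175. Ribosomal proteins stood at 0.09 without A+D 2 and 0.44 without Control 3. In the pooled O/C mixtures the activity-linked list had a median of 1.64 and the mature sensory neuron list one of 0.85, each with adjusted p = 0.0373 with an estimated correlation (up to 0.0641 without Control 1, Control 2, Control 3, O+C 2, O+C 3 or O&C 2). The remaining lists are given with their camera adjusted p, and none of them was called with an estimated correlation (adjusted p from 0.173 to 0.978). Immune cell genes had a median of -0.85 and 8 of 16 lower (5.76e-08), Lyz2 falling by 0.73 in O+C and 0.78 in O&C. Sustentacular genes had a median of -0.41 and 7 of 15 lower (1.21e-07). Sult1c1 stood at -0.80 in O+C and -0.93 in O&C, and Gpx6 at -0.88 and -0.94. Aldehyde and alcohol metabolism genes had a median of -0.38 and 12 of 18 lower (8.32e-07), Akr1b3 falling by 0.57 and 0.64, and xenobiotic metabolism genes one of -0.39, with 2 higher and 9 lower (0.000456). Bowman gland genes stood at -0.71 with 4 of 14 lower (0.00692), and the gland transcripts that split the libraries were low in 2 of the 3 O&C libraries, 1 of 3 in Control and 0 of 3 in O+C. Red blood cell genes stood at -0.68 (0.00244), horizontal basal cells at -0.47 (0.0196), endothelial and stromal cells at -0.41 (0.0177), respiratory ciliated cells at -0.33 (0.00909), ensheathing glia at -0.31 (0.0148) and globose basal cells at -0.23 (0.00591). Immediate early genes were at 0.28, with 9 higher and 1 lower (0.00027), ribosomal proteins at -0.29 (3.27e-05), mitochondrial transcripts at -0.58 (0.00692) and class I receptors at -0.65 (0.000931). Horizontal basal cells lost their camera call without Control 1, O+C 1, O+C 3 or O&C 3 (up to 0.0724), stromal cells without Control 1 (-0.23) or O+C 1, class I without Control 2 (-0.34) and both ribosomal proteins (-0.12) and mitochondrial transcripts (-0.39) without Control 3. Bowman gland stood at -0.36 without Control 3 and ensheathing glia at -0.56 without O&C 1. Not called were immature sensory neurons (-0.09), microvillar cells (-0.37), bone and muscle (-0.39), NRF2 targets (0.14), heat shock (-0.09), dorsal (0.15) and ventral zone neurons (0.01), class II receptors (-0.34), and trace amine receptors (-0.28). The circadian list had a median of -0.04, a mean of 0.05 and a test direction of higher (0.803), pseudogenes -0.28, 0.11 and higher (0.407), and vomeronasal receptors -0.03, 0.40 and higher (0.645).

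**Figure D5:**
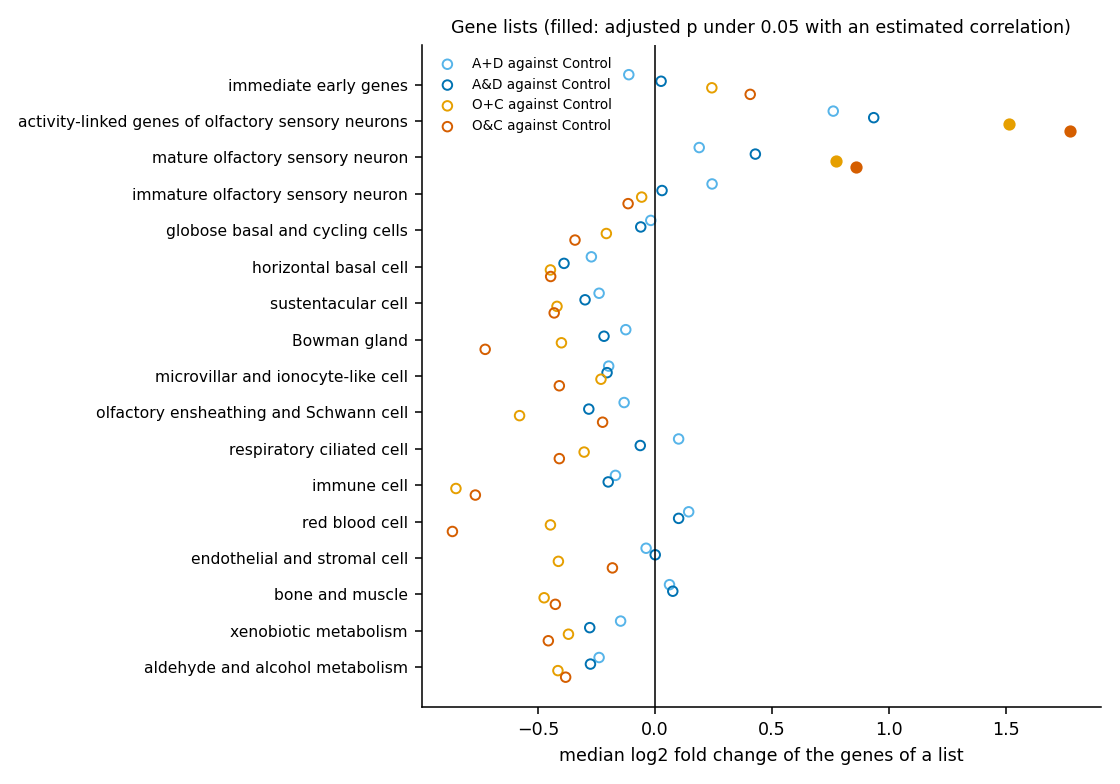
Median log2 fold change of the lists of cell types, activity and metabolism against Control in the 4 odour groups, with filled markers where the adjusted p with an estimated correlation was below 0.05. The activity-linked and mature sensory neuron lists are filled in O+C and O&C, with medians of 1.51 and 0.77, and 1.77 and 0.86.

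The pairs were then compared with each other, A/D against O/C. Olfr923 was higher in A/D by 5.48 ± 0.30 on the log2 scale, Olfr1026 by 5.13 ± 0.31, Olfr1377 by 4.82 ± 0.28, Olfr145 by 4.81 ± 0.36 and Olfr874 by 4.77 ± 0.22 (edgeR, 6 mice against 6). Olfr847 was at -4.66 ± 0.34, Olfr1170 at -3.71 ± 0.15, Olfr984 at -3.51 and Olfr1364 at -3.44 ± 0.12 (adjusted p = 1.27e-13), all higher in O/C. Olfr1167 was at -4.16, or -4.77 without A+D 3. Olfr983 was higher in A/D by 4.17 and Olfr2 stood at -2.45. Of the 867 receptors, 198 were higher and 125 lower in A/D, adjusted over the list alone, 173 and 118 over all genes, and 128 and 145 when scaled on the receptors alone. Over all genes 1296 were higher and 1736 lower, which became 1984 and 2309 without A+D 1, 678 and 1103 without A&D 1, 715 and 1118 without O+C 1, and 553 and 1167 without O&C 3. Mature sensory neuron genes were lower in A/D (median -0.46, camera 1.14e-12, and adjusted p = 0.188 with an estimated correlation), immediate early genes were at -0.32 (8.62e-07, and 0.146) and ribosomal proteins at 0.55 (7.94e-21, and 0.331). The activity-linked list was at -0.70 (1.81e-05, and 0.288), NRF2 targets at -0.29 with 1 higher and 5 lower (0.0328, and 0.437) and the circadian list at -0.06 (0.0371, and 0.309). Mitochondrial transcripts were at 1.13 with 10 of 15 higher (9.68e-09, and 0.309), red blood cells at 0.82 with 4 of 5 higher (0.000126, and 0.3) and immune cells at 0.63 with 8 of 16 higher (1.08e-06, and 0.3). Also higher in A/D by camera were respiratory ciliated cells (0.32), bone and muscle (0.32), endothelial and stromal cells (0.26), immature sensory neurons (0.24), globose basal cells (0.19), sustentacular cells (0.14), aldehyde and alcohol metabolism (0.16), class I receptors (0.43) and class II receptors (0.31), with adjusted p from 0.000541 to 0.0371, and from 0.3 to 0.572 with an estimated correlation. The mitochondrial scores of A+D 2 and A&D 1 (1.28 and 1.41) lay above those of the other A/D libraries (0.02 to 0.52), and that of O+C 3 (0.49) above those of the other O/C libraries (-0.95 to -0.81). The mitochondrial median stayed between 0.85 and 1.34 without any 1 of the 12 libraries. Without A+D 2 ribosomal proteins stood at 0.36 and immature neurons at 0.13. Aldehyde and alcohol metabolism lost its call without A+D 1, A&D 3 (0.10), O+C 3, O&C 1 or O&C 3 (up to 0.216), the circadian list without A+D 3, O+C 3 or O&C 1, NRF2 targets without A+D 2, stromal cells without O+C 1, class I without A+D 3 and class II without O&C 1 (up to 0.145). The circadian median lay between -0.15 without A+D 2 and -0.04 without A+D 3. Globose cells stood at 0.13 without A&D 3, and sustentacular cells at 0.06 without O+C 1 or O&C 3.

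All 70 receptors higher in A+D were also higher in A&D, where independent lists of these sizes would share 8.4. All 106 higher in O+C were also higher in O&C, where independent lists would share 17.5, and the 34 shared by A/D and O/C compare with 14.4. Groups simulated without effects against the same Control libraries shared 0, a value that follows from their having almost no calls and that does not measure what the shared controls add. Across receptors, which are not independent replicates, the log2 fold changes of A+D and A&D had Pearson's r = 0.832 and Spearman's rho = 0.625, those of O+C and O&C 0.903 and 0.765, and those of A/D and O/C 0.279 and 0.36. Simulated unchanged groups gave r = 0.493, 0.496 and 0.666 from the shared Control libraries alone. The covariances were 0.795, 1.1 and 0.285 against simulated ones of 0.101, 0.103 and 0.102, differences of 0.694, 1.00 and 0.183. With 3 Control libraries the controls could not be split, so part of the excess may come from them.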

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

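The tests of gland tissue, of a dilution of the A+D precipitates, of a shift limited to receptors that also respond to O/C and of the 34 receptors that respond to both pairs were chosen only after the result was seen. A test of the difference itself called the delivery effect as different between the odorant pairs for 6 receptors and Nr4a1. Of these, Olfr1426 alone kept its call without each of the 12 libraries. The log2 differences were -1.98 for Olfr1408, -1.90 for Olfr509, -1.73 for Olfr1426, -1.54 for Olfr479, -1.51 for Olfr749, -1.22 for Olfr121 and -1.50 for Nr4a1 (edgeR, n = 3 mice per group). Of these receptors Olfr1426, Olfr749 and Olfr121 were not higher in O/C. Olfr749 had a difference of 0.64 between O+C and O&C, which is part of its value, and Olfr1426 and Olfr121 had -0.03 and -0.15. With no O/C response for the delivery to alter, the values of Olfr1426 and Olfr121 largely repeat their A/D effects of -1.77 and -1.37. The median difference over the 94 receptors that respond to A/D was -0.78, which follows in part from the choice of that set, as 60 of them were not higher in O/C. Over the 34 that respond to both it was -0.58 (limma, estimated correlation p = 0.000709). In each case the level with 1 paper, against separate papers, was lower for A/D than for O/C. Olfr1426, Olfr509, Olfr749, Olfr479 and Olfr121 share reads with other genes, so these 5 differences may belong in part to those genes. Library A+D 2, which stands apart, was tested as the sole cause of the 7 calls. Without it the median size of the 7 differences was 1.03 times its value with the library, all 7 kept their direction and 4 stayed called, which argues against that library as the whole cause. No biological test separates the odorant pairs further, since each pair was given as a mixture only. In 12 of 100 splits drawn of the 12 libraries as many as the 6 receptors were called (34 at most). These splits reshuffled libraries inside each odorant pair only. The split with 34 calls kept the A+D and A&D libraries apart. Such a split carries the real A/D delivery effect, so the count does not measure chance, and chance is not excluded for it. For the 2 genes called over all genes 4 of 100 splits gave as many (5 at most), which decides nothing for the same reason.

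The second pattern is the lower level in A+D than in A&D of the receptors that respond to A/D, with a median of -0.88 on the log2 scale. Library A+D 2 as the sole cause would need the shift to end without it, and it stayed at -0.79 (limma, estimated correlation p = 4.79e-05). Gland transcripts were low in 1 of 3 libraries in both groups, so a term for them is balanced here and tests nothing. The responsive receptors were lower in A+D on both sides of that split. Their mean log2 CPM with high gland transcripts was 2.35 and 2.59 in A+D, and 3.36 and 3.25 in A&D. With low ones it was 2.38 in A+D and 3.51 in A&D. These values argue against the gland split as the source of the shift. Uneven gland tissue would also need the responsive receptors to follow the gland transcripts inside the groups. Libraries with high gland transcripts were higher by 0.12 (95% interval from -0.095 to 0.332), which is small beside the shift and argues against gland tissue as the whole cause. A dilution of the A+D precipitates by unenriched RNA would lower every responsive receptor by a like amount at a like response. At equal response the receptors shared with O/C differed from those of A/D alone by -0.48 (a rotation test gave a probability of 4e-04), which argues against dilution as the whole cause. A shift limited to the receptors shared with O/C would leave the 60 receptors of A/D alone near 0, and their median was -0.75 (limma, estimated correlation p = 2.92e-05). Of the explanations tested, none accounts for the whole pattern. The delivery itself stays open as a hypothesis, along with any unrecorded difference between the A+D and A&D mice, such as the day or the cage, that the labels do not give.

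Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For the A/D shift of -0.88 the real split was the only 1 of 10 that reached it, and the highest other value was -0.42. For the 39 receptors called between A+D and A&D it was also 1 of 10 (highest other 0), and for the 23 genes 1 of 10 (highest other 1). For the O/C shift of -0.39, 3 of 10 splits gave one as large (highest other 0.43). For the 3 receptors called between O+C and O&C 2 of 10 splits gave as many (highest other 3), and for the 0 genes, where edgeR had 766 at an unadjusted p under 0.05 and DESeq2 called 9, all 10 splits did (highest other 0).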

How the results depend on the processing

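The fits with a term for gland transcripts and on the 10 libraries that hold them were chosen only after the result was seen, and the other alternatives were planned. No shift and no correlation changed sign under any alternative run for it, and no called gene named here did so under those run for named genes, but the balance of higher and lower calls turned in places. Between A/D and O/C it went from 198 higher and 125 lower receptors to 128 and 145 when scaled on the receptors alone. For O/C it went from 133 and 149 to 150 and 31 with that scaling, to 132 and 123 with the replicate block, to 124 and 108 on the 10 libraries with gland transcripts and to 126 and 104 adjusted over all genes. It turned for O/C without Control 2, Control 3, O+C 1, O+C 3, O&C 1 or O&C 3, and for O&C from 143 and 110 to 124 and 127 without Control 1. Over all genes, the interaction went from 0 and 2 (edgeR) to 126 and 78 without a filter. RLE scaling in place of TMM moved none of the 38 summary results by more than 1.5 times, and the A/D delivery shift kept its direction and its side of the threshold throughout (-0.98 to -0.73). Except where a reason follows, the cause of a change was not tested.

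Adjusted over all genes, where more genes share the correction, the receptor counts were 46 for A+D, 21 for A+D against A&D, 0 for O+C against O&C (edgeR, 76 receptors at an unadjusted p under 0.05, DESeq2 14) and 1 for the interaction, and A+D and A&D shared 46 higher receptors. Without a filter on low counts, 885 genes were called in A+D, 610 in A&D, 208 between A+D and A&D, 204 between O+C and O&C, 204 in the interaction and 1033 in A/D. The receptor counts were 66, 27 and 28 for the delivery comparisons and the interaction, and the correlations 0.685, 0.784 and 0.395. With the stricter filter the correlations of the deliveries were 0.895 and 0.942. With the usual filter, Spearman's rho in place of Pearson's r was 0.625 and 0.765.

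DESeq2 called 235 genes in A+D, 439 in A&D, 43 between A+D and A&D, 9 between O+C and O&C, 8 in the interaction and 607 in A/D, with 14 receptors between O+C and O&C and 18 in the interaction. Fitted on the compared groups alone, which changes the estimate of the spread, the counts of genes were 368 in A&D, 2618 in O+C, 4664 in O&C, 10 between A+D and A&D and 119 in A/D. The fit called 1 receptor between O+C and O&C and left the O/C shift at -0.39 (limma, estimated correlation p = 0.0702), no longer past the threshold. This fit has no counterpart for the overlap and correlation of A/D and O/C. Scaled on the receptors alone, the O+C against O&C count was 12 and that of O/C 181.

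On the 10 libraries with gland transcripts, a smaller sample, 108 genes were called in A&D, 802 in O&C, 11 between A+D and A&D, 5 between O+C and O&C, 0 in the interaction (edgeR), 92 in A/D, 2045 in O/C and 754 between A/D and O/C. There were 139 receptors in O&C and 7 between O+C and O&C, and correlations of 0.758 and 0.794. O&C keeps 1 library in that fit, which is assumed to vary like the other groups. A gland term left 2 receptors in the interaction and moved no other summary result, though it is balanced between A+D and A&D and tests nothing there.

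With an estimated correlation in camera 0 lists were called in A+D, A&D, both delivery comparisons, the interaction, A/D, and A/D against O/C, and 2 each in O+C, O&C and O/C. The fry test called 0 in A+D, both delivery comparisons and the interaction, 1 in A/D, 2 in A&D, 6 in O+C, 12 in O&C, 14 in O/C and 15 between A/D and O/C.

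The replicate numbers do not pair the samples. Same-numbered libraries had a mean correlation of -0.03, and 1 of 15 correlated best with its own number. With the replicate number as a block 1 gene was called in the interaction and 133 in A/D, and no other summary result moved by more than 1.5 times.

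Leaving out each library in turn gave these ranges of genes called: 43 to 527 in A+D, 112 to 201 in A&D, 542 to 1206 in O+C, 1274 to 2284 in O&C, 10 to 20 between A+D and A&D, 0 to 2 between O+C and O&C, 1 to 4 in the interaction, 84 to 702 in A/D, 1854 to 2994 in O/C and 1720 to 4293 between A/D and O/C. Receptor counts ran from 0 to 10 between O+C and O&C, 1 to 6 in the interaction and 186 to 269 in O/C. Correlations ran from 0.771 to 0.842 for A+D and A&D and 0.859 to 0.9 for O+C and O&C, and the O/C shift from -0.56 to -0.29. Lists called ran from 4 to 12 between A+D and A&D (4 without A+D 2), 3 to 9 between O+C and O&C (3 without O+C 3, 5 without O&C 3) and 4 to 7 in the interaction (4 without A+D 2). No library moved the other totals of receptors called or the overlaps of higher receptors by more than 1.5 times, though the lower calls within those totals moved more, in O&C from 110 to 31 without O&C 1 and in O+C from 44 to 23 without O+C 1. The difference of the receptor share between A+D and Control ran from 0.02 without A+D 3 to 0.077 without A+D 2.

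At 1.5-fold the simulated A+D against Control comparison recovered 17.6% of the changed receptors and 6.1% of the other changed genes. These genes had a mean of at least 1 CPM. Changes of that size were thus mostly missed in that simulated comparison, in which few genes changed. Comparisons in which more genes are called can detect changes of about that size. Cdk1, for one, was called in O&C at a log2 fold change of -0.56 (edgeR adjusted p = 0.000737).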

Other observations

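The test of the mature neuron share and the split of the libraries by gland transcripts were chosen only after the result was seen. Another split of the libraries was counted for each result of a fit across genes. For the comparisons of 3 against 3 mice only 10 splits exist, which is too few for a share under 0.05. The real count of receptors was 71 in A+D, 107 in A&D, 150 in O+C and 253 in O&C against Control, each reached by 1 of 10 splits, with highest other values of 1, 1, 0 and 0. The counts over all genes were 62, 197, 1555 and 2834, each reached by 1 of 10 splits, with a highest other value of 0. The counts of gene lists called by camera with its preset correlation were 9 (1 of 10 splits, highest other 8), 10 (3 of 10, highest other 12), 16 (1 of 10, highest other 15) and 15 (2 of 10, highest other 17). For A+D against A&D 8 lists were called (6 of 10 splits, highest other 11), and for O+C against O&C 8 lists (6 of 10, highest other 12).

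Where Control was compared with 6 pooled mice, 84 splits exist by which 3 libraries serve as Control. Only the real split gave as many for the 98 receptors of A/D (1 of 84, highest other 56), the 282 receptors of O/C (1 of 84, highest other 129) and the 3292 genes of O/C (1 of 84, highest other 1073). These shares are under 0.05, but no share of splits given here is adjusted for the number of results counted. For the 235 genes of A/D 4 of 84 splits gave as many, a share under 0.05. One of them, with A+D 2, A+D 3 and A&D 1 in place of Control, called 2158, which points to a structure of the samples other than the groups. The definition of these splits was corrected after the first counts had been seen, which took the 235 genes of A/D below that share and the 17 lists of O/C above it. Chance is not excluded for the 9 lists of A/D (31 of 84 splits, highest other 14) and the 17 lists of O/C (5 of 84, highest other 17), nor for the 7 lists of the interaction (70 of 100, highest other 13). Between A/D and O/C, 100 splits were drawn, and only the real split gave as many as the 323 receptors (1 of 100, highest other 182), the 3032 genes (1 of 100, highest other 10) and the 18 lists (1 of 100, highest other 17). For the lists another split came close, and no list was called there with an estimated correlation.

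Receptors were lower in the pooled O/C mixtures than in Control for 149 genes. A loss of mature sensory neurons from the O/C tissue would lower their marker genes too, and these had a median of 0.85 (limma, adjusted p = 0.0373 with an estimated correlation, and up to 0.0641 without 6 of the 9 libraries). The precipitate is enriched for activated cells, and the activity-linked genes rose as well, so a rise of neuron markers in it does not measure the neurons in the tissue. The test decides nothing, and such a loss stays open. An even fall of all receptors that do not respond was to be tested by scaling on the receptors alone, which left 31 lower calls. That scaling moves every receptor up alike, by a median of 0.27 on the log2 scale, so fewer lower calls follow from it in part by construction and the test decides nothing. The receptors not higher had medians of -0.70 in class I and -0.45 in class II, a difference that was not tested. Whether the fall was even stays open. A larger share of the precipitate taken up by transcripts of activated neurons could lower the others, and the design does not separate that from lower levels in each neuron.

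Octanal and decanal are both straight-chain aldehydes, and 34 receptors were higher in both odorant pairs. Those 34 had a median delivery shift of -1.21 between A+D and A&D, and the 60 of A/D alone one of -0.75. At equal response the difference was -0.48 (a rotation test gave a probability of 4e-04). A hypothesis from these values is that the response to decanal may be lowered more than that to acetophenone when both share a paper. It assumes that the 34 shared receptors respond to decanal rather than acetophenone, which these data do not show. Between O+C and O&C, where no decanal was given, the 34 also had the lower median. It was -0.47, against -0.35 for the 99 receptors of O/C alone, a difference that was not tested. The 4 acetophenone receptors had a median shift of -0.52 (limma, estimated correlation p = 0.0348, fry p = 0.0721), with 3 of 4 lower, so that a lower response to acetophenone is not ruled out. No group received 1 odorant alone, so the hypothesis was not tested on other data.

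Odorant binding proteins, lipocalins and other gland products separated 10 libraries from 5, across the groups. Obp1a lay at 16.9 to 341 CPM in the 10 and at 0.169 to 1.01 CPM in the 5. The gland products Bpifb3 (1890 to 4460 and 2260 to 3460 CPM), Bpifb9a (0.0414 to 106 and 0 to 307 CPM) and Bpifb9b (0.414 to 342 and 0.0833 to 918 CPM) were not split. Libraries with these transcripts low numbered 1 of 3 in Control, A+D and A&D, 0 of 3 in O+C and 2 of 3 in O&C.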
